A study of Mus musculus with 8 samples.

How the data were processed

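RNA of sorted mouse liver endothelial cells was measured on 8 Affymetrix arrays, 4 of YFP+ (marrow-derived) and 4 of YFP- (resident) cells. Per the labels' protocols, livers were digested with collagenase, red cells were lysed, cells negative for CD45 and positive for CD31 and CD146 were sorted and then divided by YFP, RNA was isolated with the PicoPure kit, and biotin-labelled cRNA was made from 100 pg of total RNA with the 3' IVT Pico kit. The array model, the summarization and normalization software, any background correction, the genome build and the annotation are not given in the sources used here.

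The authors deposited normalized intensity values on a linear scale for each probe set and array, and nearly equal quartiles on all 8 arrays show that the arrays were scaled to each other. Of the deposited tables, 1 holds 29129 and the other 28838 entries, with identical values for each of the 8 arrays where both have them. The larger table also holds, per the file headers, the authors' means of each group, their fold (the ratio of the YFP+ to the YFP- mean) and an unadjusted p-value from a test that is not named. Samples were grouped by the titles in the labels, which number 4 biological replicates in each group. The column headers of the larger table also give the same set of numbers to both groups, so that same-numbered sorts may share a mouse. No source says that a number marks 1 mouse, so the main fit left the arrays unpaired, and p-values measure the spread between these samples.

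Values were log2 transformed without further normalization. Of 22206 probe sets of genes, 3 had a missing value and 22203 were used, and 6923 control and reporter entries were left out of the tests. Gene names came from the deposited annotation column, in which 7194 entries are truncated. A single symbol was found for 21371 probe sets, several for 829 and none for 3. Entrez numbers matched a RefSeq table of assembly GRCm38.p6 for 20402 probe sets, which updated 899 symbols and gave chromosome names; no coordinates are given, since the build of the array annotation is not stated. Only probe sets with 1 symbol were tested, and for 131 genes with several the brightest over all 8 arrays was taken, which gave 21161 genes. No filter on dim genes was used.

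The comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default settings, no covariate), two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05; a second count took genes that also differed at least 2-fold. SDs are over the 4 arrays of a group and SEs are limma's. For 42 gene lists, 20 of cell types and 22 of processes with 608 measured entries and 560 distinct genes, camera with its preset correlation of 0.01 compared each list with all other genes, adjusted over the 42 lists, with an estimated correlation as an alternative; members were also adjusted over the list alone. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for reading the tables and for plots. The lists, tests, alternatives and the rule for named genes were set before the data were examined, except the tests of candidate sources, the alternative without YFP+ replicates 2 and 3 and the other observations, which were chosen after results were seen. That rule took the 10 genes with the largest rise and the 10 with the largest fall among called genes with non-overlapping groups, passing over predicted genes, up to 4 members of each list with the smallest adjusted p, the genes of the sort markers, sex-linked genes and reporter features; of the list members it took, those that matter are named. Xist was not analysed here. Genes named outside the rule stand under other observations.

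The procedure was tested on simulated data for this comparison, with 21161 genes of which 200 were changed, 50 of each size. At log2 differences of 0.5, 1, 2 and 3 it recovered 14%, 66%, 100% and 98% of them, with 7 false among 146 calls, and camera called the 1 list that had been lowered by 0.4 and no list when none was changed. The simulated genes were drawn independently of each other, whereas the estimated correlation within the measured pan-leukocyte list was 0.60. False list calls that arise from correlated genes were therefore not tested. Each simulated gene also had the same SD in both groups, whereas the measured median SD was 0.169 in YFP- and 0.234 in YFP+ cells. Recovery and false calls under unequal spread were thus not tested either. Array depth has no count, and the number of arrays sets the precision. The share of an array's probe sets above the 95th percentile of its negative controls was 13.8% to 15.5% on YFP- and 14.5% to 19.1% on YFP+ arrays. Alternatives were the replicate number as a block, quantile and cyclic loess normalization, leaving out dim genes, the mean of a gene's probe sets, all probe sets apart, trended and robust eBayes, array weights, treat, fry, and leaving out each array in turn.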

Results

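Gene expression was measured on Affymetrix arrays in endothelial cells sorted from the livers of mouse bone-marrow chimeras. The recipients, 8-week-old C57BL/6N mice, had received 9 Gy of radiation in 2 doses of 4.5 Gy and then 5000 YFP-labelled LSK cells, the lineage-negative, Sca-1-positive, Kit-positive fraction of marrow that holds blood stem and progenitor cells. After 1 month, liver cells negative for CD45, the surface marker of leukocytes, and positive for the endothelial markers CD31 and CD146 were sorted. They were then divided by YFP into marrow-derived (YFP+) and resident (YFP-) cells. Each population was measured on 4 arrays, which the labels call biological replicates, so there are 8 arrays and 1 comparison, and the number of arrays limits its precision. It asks how the transcripts of liver endothelial cells of marrow origin differ from those of the resident cells around them.

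All values are the authors' normalized intensities on the log2 scale, without background subtraction that any source states. The negative controls had median intensities of 119.5 to 128 units on the YFP- arrays and of 103 to 113 units on the YFP+ arrays. Folds of dim genes are therefore probably understated. The controls did not overlap between the groups, and whether this difference bears on dim genes was not tested. The arrays had nearly equal medians, from 160.1 to 166 intensity units. The first principal component, with 33.7% of the variance, separated the 4 YFP+ from the 4 YFP- arrays. The second, with 26.1%, set YFP+ replicate 3 (55.4) apart from all other arrays (-18.3 to 3.04). Resident samples were more alike: the mean correlation of a YFP- array with its own group lay between 0.962 and 0.969, and that of a YFP+ array between 0.901 and 0.941. YFP+ replicate 3 had the lowest of these values and the highest median of the background control probes, 87.5 units against 76.0 to 81.5 units on the other arrays.

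YFP+ cells carried far more of a set of blood-cell, platelet and biliary transcripts than YFP- cells, while a smaller set of genes was modestly lower in them. Of 21161 genes tested, 340 differed at an adjusted p under 0.05 (limma, Benjamini-Hochberg), 269 of them higher and 71 lower in YFP+ cells. The median log2 difference was 1.33 among the higher genes and -0.75 among the lower ones. At least 2-fold differences were found for 205 genes, 199 higher and 6 lower. In 338 of the 340 genes the groups did not overlap, as was the case for 8.62% of all genes against 2.86% by chance. The count depended on single arrays. It was 635 without YFP+ replicate 3, 329 without YFP+ replicate 2, 182 and 183 without YFP+ replicates 1 and 4, and 136, 115, 140 and 130 without YFP- replicates 1 to 4. The count of genes at 2-fold or more moved likewise, to 342 without YFP+ replicate 3 and to 118, 101, 107 and 105 without YFP- replicates 1 to 4. The lower genes were the less stable part: they numbered 39 after cyclic loess normalization, 133 and 47 without YFP+ replicates 3 and 2, 23 and 36 without YFP+ replicates 1 and 4, and 12, 8, 23 and 19 without YFP- replicates 1 to 4. With array weights 695 genes were called, 176 of them lower. Of 64 genes with a call that are named here, all kept their direction without each array in turn and 28 kept their call. Where the groups do not overlap, as in 338 of the 340 genes, leaving out an array cannot turn the direction. That the direction was kept is therefore no sign of stability.

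**Figure D1:**
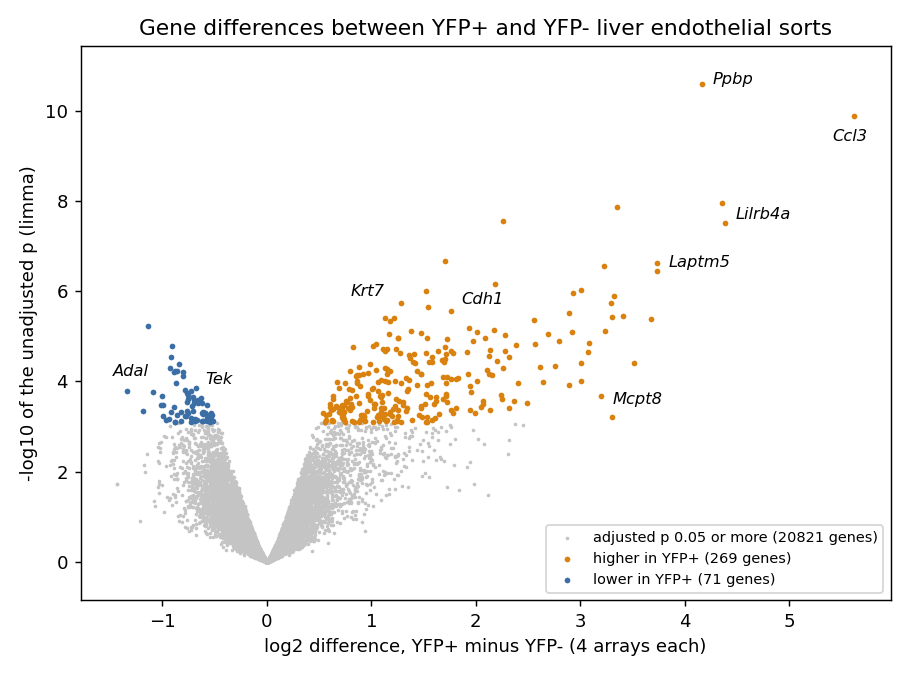
Each point is 1 gene, placed by its log2 difference (YFP+ minus YFP-, 4 arrays each) and the negative log10 of its unadjusted limma p. The 269 genes higher in YFP+ cells reach a log2 difference of 5.62, for Ccl3, while the 71 lower genes go no further than -1.34, for Adal.

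Ccl3, which encodes a chemokine that attracts leukocytes, had the largest measured difference. Its mean log2 intensity was 6.43 ± 0.10 in YFP- and 12.05 ± 0.50 in YFP+ cells (SD, n = 4), a measured 49.1-fold difference (limma adjusted p = 1.41e-06). Lilrb4a and Lilr4b, which encode leukocyte immunoglobulin-like receptors, were 20.8-fold and 20.5-fold higher. Ppbp, a chemokine of platelet granules, was 17.9-fold higher, and its YFP+ values varied little (SD 0.17, n = 4). Laptm5, a lysosomal protein of blood cells, and Cd69, an early activation antigen of lymphocytes, were both 13.3-fold higher. All 10 genes with the largest differences lay below the 95th percentile of the negative controls on every YFP- array, as 236 of the 269 higher genes and 82.3% of all genes did, and 6 of the 10 (Ccl3, Lilrb4a, Ppbp, Cd69, Nlrp3 and Aqp9) also below their median. Folds of such genes are probably understated, and their order is not settled. The other genes among these 10 were Rgs1 (12.8-fold), the inflammasome sensor Nlrp3 (11.4-fold), the channel gene Aqp9 (10.6-fold) and Plek (10.2-fold), which encodes a major protein kinase C substrate of platelets. Adjusted p-values of these 10 genes from limma lay between 5.50e-07 for Ppbp and 0.00995 for Nlrp3. Ccl3, Nlrp3 and Plek lie on chromosome 11, Lilrb4a and Lilr4b on chromosome 10, Ppbp on chromosome 5, Laptm5 on chromosome 4, Cd69 on chromosome 6, Rgs1 on chromosome 1 and Aqp9 on chromosome 9.

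The genes that were lower in YFP+ cells changed by smaller amounts. Adal, a deaminase-like gene, fell by 1.34 on the log2 scale (SE 0.23, limma adjusted p = 0.0224). Plppr5 fell by 1.19, Egfem1 by 1.14, Ica1 by 1.10 and Spats2 by 1.02, all on the log2 scale. Dennd5b and Prpf3 had log2 differences of -0.99 each, Ptdss2 of -0.97, Pms2, a DNA mismatch repair gene, of -0.93, and Srgap1 of -0.92. Limma adjusted p-values of these 10 genes lay between 0.00447 for Egfem1 and 0.0486 for Ptdss2.

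Of 14 measured pan-leukocyte genes, 6 were called higher in the YFP+ cells over all genes tested, 10 adjusted over the list alone, although the sort had excluded cells with surface CD45. All 14 had positive differences. The list was called by camera with its preset correlation (adjusted p = 7.97e-15), with an adjusted p = 0.113 with an estimated correlation. Cd53 was 9.86-fold, the adaptor gene Tyrobp 8.06-fold and Spi1, which encodes the myeloid transcription factor PU.1, 8.50-fold higher. Their YFP+ SDs (0.92, 1.10 and 0.97 log2, n = 4) were far above those in YFP- cells (0.09, 0.13 and 0.27). The transcript of Ptprc, the gene of CD45, had a mean log2 intensity of 8.79 ± 1.18 in YFP+ and 7.28 ± 0.36 in YFP- cells (SD, n = 4), which did not pass the test (limma adjusted p = 0.181).

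Lists of several blood lineages held called genes. On the mast cell and basophil list 3 of 9 genes were called, 7 adjusted over the list alone. Mcpt8, a protease gene of basophils, was 9.21-fold, the IgE receptor gene Fcer1a 3.78-fold and the histamine-forming Hdc 2.56-fold higher, while Cpa3 had a 5.19-fold difference that missed the threshold (limma adjusted p = 0.0532). The monocyte list had 4 of 12 genes called (7 over the list alone), namely Lyz2, Plac8, Itgam and Ms4a6c, at 3.39, 2.78, 3.84 and 2.29 fold. The Kupffer cell and macrophage list had 4 of 14 (5 over the list alone), namely Cd5l, C1qa, Fcna and Csf1r, at 2.88, 2.98, 1.72 and 2.32 fold. On the neutrophil list, 1 of 12 genes was called (2 over the list alone), the chemokine receptor gene Cxcr2 at 4.84-fold. No gene of the T and natural killer cell list (13 measured, 5 over the list alone) or of the B and plasma cell list (10 measured, 0 over the list alone) was called. Camera called these 6 lists higher with its preset correlation. Their estimated-correlation values were an adjusted p = 0.113 with an estimated correlation for the mast cell, monocyte, Kupffer cell, neutrophil and B cell lists and 0.153 for the T cell list. The B and plasma cell call ended without YFP- replicate 4 or YFP+ replicate 1 (camera adjusted p = 0.0754 and 0.0653) and with dim genes left out (0.238).

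The call of the platelet genes did not depend on the correlation setting, although the pan-leukocyte list had the lower camera adjusted p with the preset one. All 11 measured genes of the megakaryocyte and platelet list had positive differences, and 3 were called, 5 adjusted over the list alone. Besides Ppbp these were the platelet chemokine gene Pf4, 4.78-fold higher (limma adjusted p = 0.000109), and the collagen receptor gene Gp6, 2.01-fold higher. It was the 1 list of 42 that stayed called with an estimated correlation (camera adjusted p = 0.0154), which was -0.013 for this list. Its mean log2 difference (0.95) lay well above its median (0.41).

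Some epithelial genes were called higher as well. Of the 10 measured bile duct genes, all had positive differences and 6 were called (7 adjusted over the list alone). Krt7 and Krt19, keratin genes of bile duct epithelium, were 2.43-fold and 2.22-fold higher, Krt18 was 3.44-fold and the cadherin gene Cdh1 3.38-fold higher. On the hepatocyte list, 3 of 17 genes were called (4 over the list alone). Alb, the gene of albumin, was 2.02-fold, Ttr 2.79-fold and Ambp 2.46-fold higher, and Alb stood at a log2 intensity of 10.72 ± 0.31 in YFP- cells already (SD, n = 4). Camera called both lists with its preset correlation, and neither with an estimated one (adjusted p = 0.113 for bile duct and 0.166 for hepatocyte genes with an estimated correlation). In fry the hepatocyte list missed the threshold (adjusted p = 0.0563).

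**Figure D2:**
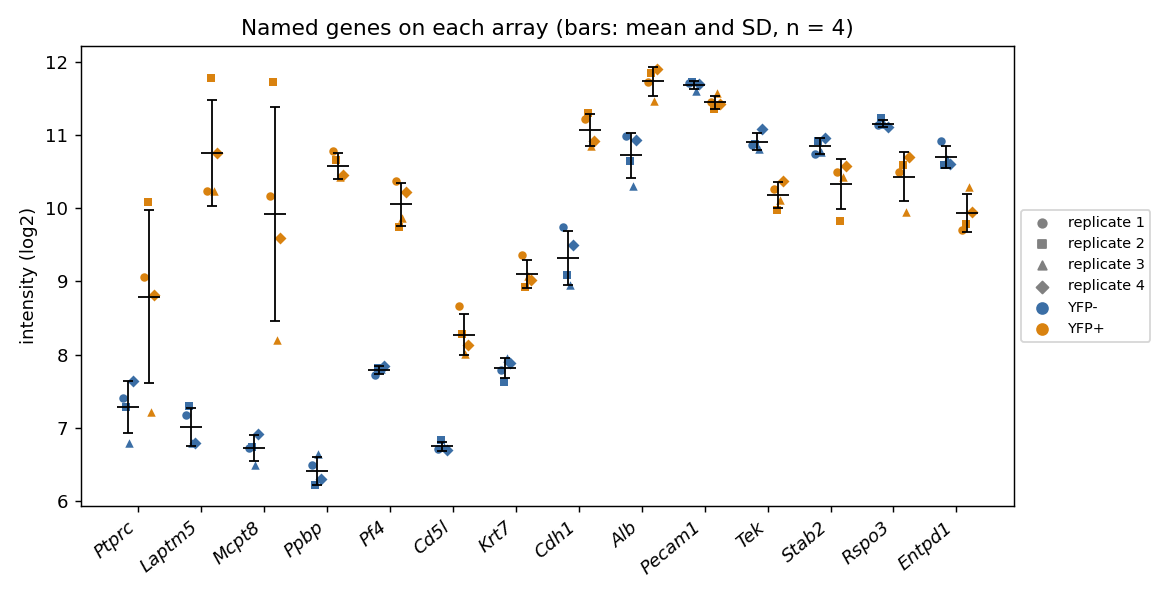
Log2 intensity of 14 named genes on each array, with blue for YFP- and orange for YFP+, a symbol for each replicate number, and the mean with its SD (n = 4). Mcpt8 and Ptprc spread widely over the YFP+ arrays (SD 1.46 and 1.18) while Ppbp does not (SD 0.17), and the endothelial genes at the right differ by less than the blood-cell genes at the left.

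Endothelial transcripts stayed at high levels in the YFP+ cells and had mostly negative differences. All 19 measured pan-endothelial genes had negative differences, with a median of -0.31, but only Tek, the angiopoietin receptor gene, was called, 1.65-fold lower (limma adjusted p = 0.0224); adjusted over the list alone, 8 were lower. Flt1, a VEGF receptor gene, had a difference of -0.57 that missed the threshold (limma adjusted p = 0.0663). The sort markers gave -0.23 for Pecam1 (limma adjusted p = 0.367) and -0.63 for Mcam (limma adjusted p = 0.297). Of 20 liver sinusoidal genes, 19 had negative differences (median -0.28) and none was called, nor over the list alone; the hyaluronan receptor gene Stab2 had a difference of -0.51. Pericentral (median -0.51) and periportal (median -0.42) endothelial genes had 10 measured members each and no call over all genes, and 6 each adjusted over the list alone. The pericentral Wnt signalling genes Rspo3 and Wnt9b had differences of -0.72 and -0.51 (limma adjusted p = 0.0601 for both), and the periportal Efnb2 of -0.47. Camera called these 4 lists lower with its preset correlation. With an estimated correlation the adjusted p was 0.116 for pan-endothelial, 0.113 for sinusoidal and pericentral and 0.147 for periportal genes.

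Arrays with more leukocyte signal had less endothelial signal. On YFP+ replicates 1 to 4 the pan-leukocyte list mean was 8.67, 9.83, 8.17 and 8.79 log2, and the pan-endothelial mean was 10.49, 10.20, 10.61 and 10.42. On the YFP- arrays the pan-leukocyte mean lay between 7.03 and 7.28 and the pan-endothelial mean between 10.76 and 10.80. The megakaryocyte and platelet mean varied little over the YFP+ arrays (8.60, 8.50, 8.53 and 8.35), and the bile duct mean was lowest on replicate 2 (9.27, 8.58, 8.87 and 9.26).

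**Figure D3:**
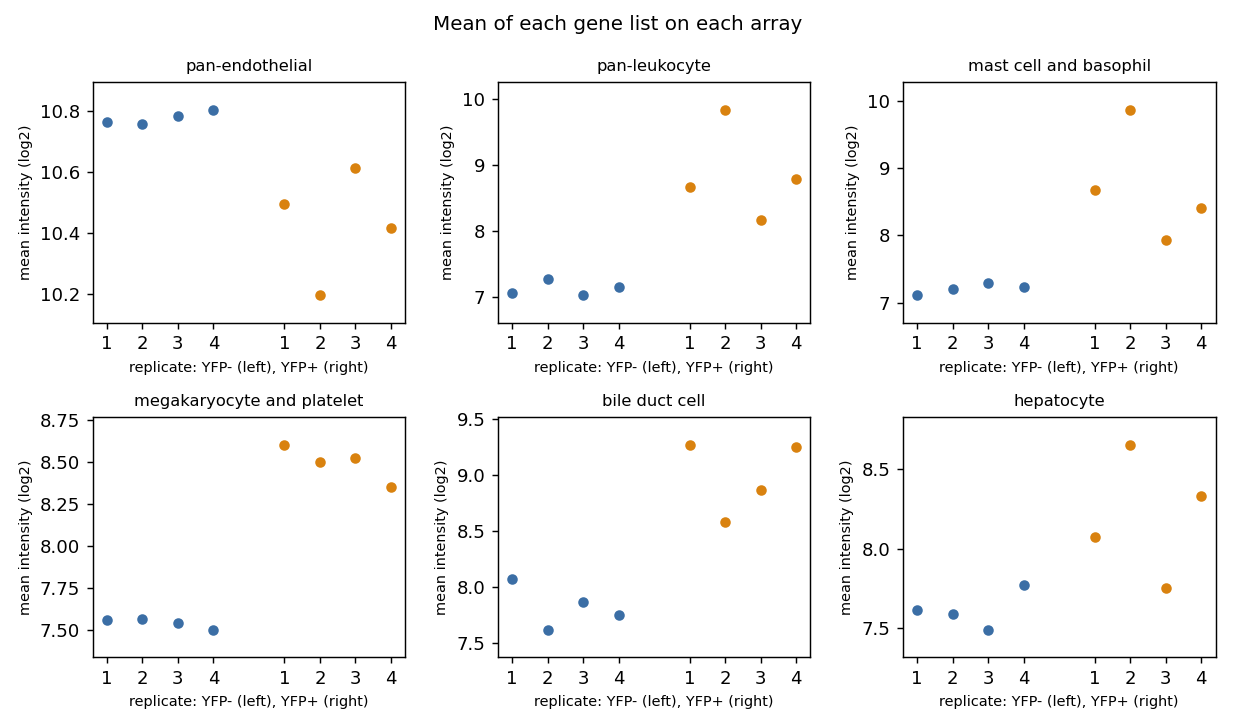
Mean log2 intensity of 6 gene lists on each array, YFP- in blue at the left and YFP+ in orange at the right of each panel, with replicate numbers below; the axes of the panels differ. On YFP+ replicate 2 the pan-leukocyte mean is highest (9.83) and the pan-endothelial mean lowest (10.20).

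Camera called 4 lists of processes higher with its preset correlation, with an adjusted p = 0.113 with an estimated correlation for each. Of 9 measured genes of MHC class II presentation, all had positive differences and 3 were called (7 adjusted over the list alone): H2-DMa and H2-Ab1 were 2.06-fold and 2.08-fold and H2-DMb1 was 2.99-fold higher. Immediate early and stress genes had 2 of 18 called, Ier2 at 2.58-fold and Jund at 1.81-fold (9 higher and 1 lower over the list alone). Glycolysis and hypoxia genes had 2 of 17 called (2 over the list alone), the glucose transporter gene Slc2a1 at 2.12-fold and Pfkp at 3.21-fold. Ribosomal protein genes had 1 of 16 called (9 over the list alone), Rpl5 at 1.45-fold, with 16 positive differences and a median of 0.33. Class II genes are characteristic of antigen-presenting blood cells, and the pan-leukocyte mean was higher on each YFP+ array than on any YFP- array. On YFP+ replicates 1 to 4 the class II list mean was 8.50, 8.69, 8.12 and 7.96 log2, that of immediate early genes 9.82, 9.96, 9.82 and 9.74, and that of glycolysis genes 8.59, 8.88, 8.59 and 8.71, each highest on replicate 2 like the pan-leukocyte mean (9.83). The match did not extend to the other arrays: class II and immediate early genes were lowest on replicate 4, where the pan-leukocyte mean (8.79) was not. The ribosomal protein mean was 11.11, 11.11, 10.92 and 11.03, and did not stand out on replicate 2.

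Camera called 4 more process lists lower with its preset correlation. None stayed called with an estimated correlation, where the adjusted p was 0.316 for TGF-beta and BMP signalling and 0.113 for the coagulation, scavenger receptor and p53 lists. In the coagulation and haemostasis list 1 of 13 genes was called (6 lower and 1 higher over the list alone), Entpd1, an enzyme that degrades extracellular ATP, at 1.70-fold lower. Scavenger receptor genes (11 measured) and TGF-beta and BMP signalling genes (15 measured) had no call over all genes, and 3 and 1 lower over the list alone. The p53 target list had a median difference of -0.21 although its called member of 23, Perp, an apoptosis-associated membrane protein, was 2.13-fold higher; over the list alone 1 was higher and 1 lower. The p53 call ended without YFP- replicate 1 or YFP+ replicate 2 (camera adjusted p = 0.0619 and 0.0580), after cyclic loess (0.0544) and with dim genes left out (0.0641). The TGF-beta call ended without YFP- replicate 3 or YFP+ replicate 2 (0.0727 and 0.210), after cyclic loess (0.0842), with dim genes left out (0.149), with array weights (0.0566) and in fry (0.145). The scavenger receptor call ended without YFP+ replicate 3 (0.120), with dim genes left out (0.127) and with array weights (0.0637).

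**Figure D4:**
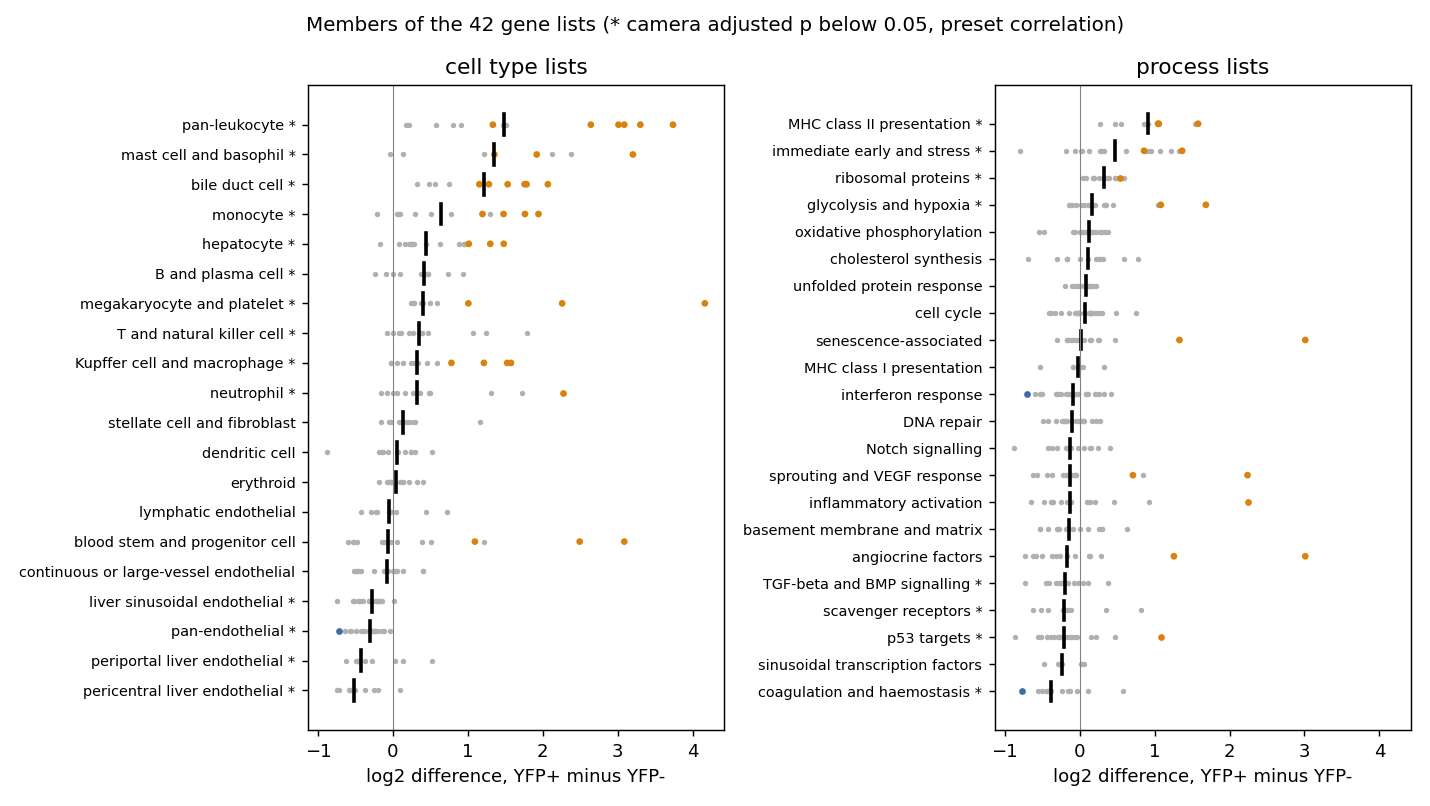
Log2 differences (YFP+ minus YFP-) of the measured members of the 42 gene lists; coloured points passed the threshold (orange higher, blue lower), grey points did not, black bars are list medians and asterisks mark the lists called by camera with its preset correlation. The pan-leukocyte list has the highest median (1.48) and the pericentral list the lowest (-0.51).

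The other 20 lists were not called, with camera adjusted p-values from 0.0781 for continuous or large-vessel endothelial genes to 0.742 for MHC class I presentation. Single members were called nevertheless. On the senescence-associated list (17 measured, 2 called and 2 over the list alone), the inflammatory cytokine genes Il6 and Il1b were 8.06-fold and 2.52-fold higher. On YFP+ replicates 1 to 4, Il6 stood at 9.09, 10.71, 7.69 and 9.40 log2, the same order of arrays as the pan-leukocyte mean (8.67, 9.83, 8.17 and 8.79), and Il1b was likewise highest on replicate 2 (8.91). Il6 and Igf1, the latter 2.39-fold higher, were the called members among 15 angiocrine factors (2 higher and 6 lower over the list alone). Cxcr4, a chemokine receptor gene, at 4.73-fold and Vegfa at 1.64-fold were those among 16 genes of sprouting and VEGF response (3 higher and 4 lower over the list alone). Tnfaip3, an inhibitor of NF-kappaB signalling, was 4.76-fold higher and the 1 called of 17 genes of inflammatory activation (2 over the list alone). Of 17 blood stem and progenitor genes, Spi1, Runx1 (5.63-fold) and Slamf1 (2.13-fold) were higher (4 higher and 1 lower over the list alone). Stat2, a transcription factor of the interferon response, was 1.63-fold lower and the 1 called of 24 genes on its list (1 over the list alone). Medians and means differed in sign for blood stem and progenitor genes (-0.07 and 0.36), inflammatory activation (-0.13 and 0.05), sprouting (-0.13 and 0.04) and angiocrine factors (-0.17 and 0.07). Camera's direction was up for the first of these and down for the others. All 4 medians moved by over 1.5 times without single arrays. That of blood stem and progenitor genes was 0.01 and -0.11 without YFP+ replicates 4 and 3, and between -0.04 and -0.01 without YFP+ replicate 1 or 2 or YFP- replicate 2 or 4. That of inflammatory activation was -0.26 and -0.07 without YFP+ replicates 1 and 2 and -0.07 and -0.25 without YFP- replicates 1 and 2. Without YFP+ replicates 1 to 4, that of sprouting was -0.20, -0.07, -0.27 and -0.06 (and -0.08 after cyclic loess), and that of angiocrine factors was -0.06, -0.32 and -0.11 without YFP+ replicates 2, 3 and 4.

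No member was called on the remaining 14 of these lists. Over the list alone, 5 of 16 continuous or large-vessel endothelial genes were lower (median -0.08), as were 1 of 12 dendritic cell genes (0.06) and 1 of 7 sinusoidal transcription factors (-0.24), while of 9 lymphatic endothelial genes 1 was higher and 1 lower (-0.06). No gene passed even over the list alone among those of erythroid cells (12 measured, median 0.04), stellate cells and fibroblasts (13, 0.14), cell cycle (27, 0.07), DNA repair (19, -0.10), MHC class I (8, -0.02), Notch signalling (14, -0.13), basement membrane and matrix (16, -0.14), oxidative phosphorylation (19, 0.13), cholesterol synthesis (13, 0.12) or the unfolded protein response (14, 0.08). All 14 medians moved by over 1.5 times without at least 1 array. That of continuous endothelial genes was -0.17, -0.04 and -0.19 without YFP+ replicates 1, 2 and 3 and -0.14 without YFP- replicate 4, and that of sinusoidal transcription factors was -0.08 without YFP+ replicate 2 and -0.13 without YFP- replicate 1. Without 1 array the median ranged from -0.03 (YFP+ replicate 2) to 0.12 (YFP+ replicate 3) for dendritic cell genes, from -0.19 (YFP+ replicate 3) to 0.04 (YFP+ replicate 1) for lymphatic genes and from -0.04 (YFP+ replicate 3) to 0.10 (YFP- replicate 4) for erythroid genes. That of MHC class I genes was 0.04 after cyclic loess. Other settings called some of these lists. The continuous endothelial list passed without YFP- replicate 4 or YFP+ replicate 1 (camera adjusted p = 0.0327 and 0.0317) and with trended and robust eBayes (0.0442), and the stellate list without YFP- replicate 1 or YFP+ replicate 3 (0.0333 and 0.0241) and with array weights (0.0281). Oxidative phosphorylation passed with all arrays after cyclic loess (0.00846), with dim genes left out (0.0377) and with array weights (0.0433), and also without YFP+ replicate 3 (0.0272), as did the matrix list in that last case (0.0489).

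As a check of the samples, Y-linked genes were read in both populations. Ddx3y, Eif2s3y, Kdm5d and Uty had log2 differences of 0.08, -0.24, 0.10 and 0.02, and none passed the test (limma adjusted p = 0.864, 0.353, 0.867 and 0.969). In the authors' deposited table, 2580 of 22203 gene probe sets had an unadjusted p-value under 0.05, of which 233 had a fold of at least 2 higher and 12 lower in YFP+ cells. None of those deposited p-values passed 0.05 after Benjamini-Hochberg adjustment; with limma on the log2 values, 2849 genes had an unadjusted p under 0.05.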

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

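The tests of the sources of blood-cell, bile duct and hepatocyte genes were chosen after the results were seen; those of other splits of the arrays, of a common shift of endothelial genes and of cyclic loess were not.

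Of the 35 splits of the 8 arrays into 4 and 4, only the real one gave 340 genes, or 205 at 2-fold or more, and the highest other split gave 1 in both cases. Every other split mixes arrays of both groups on each side, which adds the group difference to the spread within a side. The splits therefore show that the counts go with the real grouping, but they cannot by themselves exclude chance. For the 22 gene lists the real split was again the 1 with the most, and the highest other split gave 21. That one belongs to the 16 splits that exchange 1 array of each group, which gave 1 to 21 lists and keep most of the real grouping. The 18 splits with 2 arrays of each group on either side gave 0 to 4.

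In the YFP+ sorts, whose CD45 gate would remove most leukocytes, 6 of 14 pan-leukocyte, 3 of 9 mast cell, 4 of 12 monocyte, 4 of 14 Kupffer cell and 1 of 12 neutrophil genes were called higher, and none of 13 T and natural killer or 10 B cell genes, and the camera calls of these 7 lists were lost with an estimated correlation (adjusted p = 0.153 with an estimated correlation for T cells and 0.113 for the others). The tables argue against the background or quality of YFP+ replicate 3 as the cause, since the lowest pan-leukocyte mean of the other 3 YFP+ arrays was 1.39 log2 above the highest YFP- mean. Basophils or mast cells in the sort (Mcpt8 at 9.92, Laptm5 at 10.75 and Ccl3 at 12.05 log2 in YFP+ cells; 1 member of either list is on another list, and 2 pan-leukocyte and 3 mast cell members lay above the median gene level in YFP- cells) are not singled out: replicate 2 was highest in their genes and in pan-leukocyte genes, but 4 of 8 other cell type lists called higher also peaked there (monocyte 8.16, neutrophil 7.58, T and natural killer cell 7.41 and hepatocyte 8.65). The platelet genes showed a mean slope of 0.00933 ± 0.079 (SE over 11 members) on the mast cell mean over the 4 YFP+ arrays, where a change in proportion would give 0.629, but without replicate 2 the error grew to 0.252, so that a shared source stays open. Such cells cannot be told apart from marrow-derived endothelial cells that keep blood-cell transcripts, since on replicate 2 the pan-endothelial mean differed from that of YFP- cells by only -0.58 log2, which both would give, and a true difference of origin stays open and untested.

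In YFP+ cells 6 of 10 bile duct and 3 of 17 hepatocyte genes were called higher, but both lists lost their camera calls with an estimated correlation (adjusted p = 0.113 and 0.166 with an estimated correlation), and the hepatocyte list missed the threshold in fry (adjusted p = 0.0563). As a list, hepatocyte genes moved with the pan-leukocyte genes over the 4 YFP+ arrays (mean slope 0.52 ± 0.10, SE over 17 members, and from 0.43 to 0.85 without 1 array). They may therefore come with the blood-cell genes, although 4 arrays and genes that are not independent make this a hypothesis only. The 3 called members were highest on replicate 4 (Alb 11.90, Ttr 10.20 and Ambp 10.61 log2), not on replicate 2 (11.85, 9.79 and 9.66). For these called genes the slope of the list thus shows no shared source. Whether bile duct genes come with the blood-cell genes cannot be told apart from another source: their slope was -0.26 ± 0.112 (SE over 10 members) with all 4 arrays and 0.68 without replicate 2, so that its sign rests on that array. That 10 of 10 bile duct members had positive differences, with Krt18 at 10.20 and Cdh1 at 11.07 log2, is the pattern itself and does not separate bile duct cells or their RNA, which the CD31 and CD146 gates would mostly remove, from expression by the YFP+ cells (no member is on another list, and 6 lay above the median gene level in YFP- cells). A true difference of the marrow-derived cells stays open and untested.

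Endothelial genes had mostly negative differences in YFP+ cells, with 1 of 19 pan-endothelial and none of 20 sinusoidal genes called, and the camera calls of both lists were lost with an estimated correlation (adjusted p = 0.116 and 0.113 with an estimated correlation). A remaining shift between the arrays is argued against as the whole cause, since the pan-endothelial median was -0.26 after cyclic loess and -0.31 without it. The deposited values were normalized already, so an effect of the authors' own normalization was not tested. Dilution by RNA of other cells may account for these differences. Of 39 pan-endothelial and sinusoidal members, 1 had a 95% interval that excluded their common median of -0.30. Up to 4 would be chance if genes were independent, but the 2 lists had estimated correlations of 0.369 and 0.206. The median also came from these same genes, so the count cannot decide for dilution. The intervals are wide (median half-widths of 0.290 and 0.296), and the mean differences of continuous (-0.12 ± 0.075, SE over members) and lymphatic endothelial genes (-0.01 ± 0.122) lay above that median, so that a shift shared by every endothelial gene is not shown. A difference of marrow-derived from resident endothelium stays open and untested.

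In 6 of 162 sets of 4 values (3.70%, against about 5% by chance) 1 array stood far from the other 3. In YFP- cells these were Lilrb4a on replicate 3 (6.87 log2, others 6.54 to 6.58), Egfem1 on replicate 4 (7.91, others 7.53 to 7.59), Runx1 on replicate 3 (6.45, others 6.88 to 6.94) and Slc2a1 on replicate 4 (9.16, others 8.32 to 8.37). In YFP+ cells they were Fcna on replicate 1 (8.20, others 7.73 to 7.76) and Cxcr4 on replicate 2 (11.03, others 8.94 to 9.23). Among 82 reporter features of the array, which the comparisons leave out and which fall into 65 distinct sets of values, 3 sets were higher in YFP+ cells, at 3.82, 3.43 and 3.09 fold (limma adjusted p = 0.0164, 0.0188 and 0.0275). Their exact permutation p of 0.0286, the smallest that 4 against 4 arrays can give, does not set them apart, since 1 other set with a 1.10-fold difference had the same (limma adjusted p = 0.643). The other sets differed by between -0.16 and 0.28 log2, and what these features detect is not given in the sources used here.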

How the results depend on the processing

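The alternative without YFP+ replicates 2 and 3 was chosen after seeing the data. No list call turned direction, nor did any of the 64 calls of genes named in the report. For genes whose groups do not overlap, leaving arrays out cannot turn the direction. Genes named only under other observations were run, if at all, after quantile normalization and cyclic loess alone. The medians of 6 lists without a call changed sign under at least 1 of 10 scalings or omissions, among them the senescence-associated list, from 0.01 to -0.02 after quantile normalization and -0.04 without YFP+ replicate 3. Leaving out 1 array gave 115 to 635 genes, 101 to 342 genes at 2-fold or more and 20 to 24 lists. Array weights gave 695 (519 higher and 176 lower) and 329 genes and 22 lists, and omitting both YFP+ replicates gave 586, 346 and 20; the cause was not tested beyond the low weight of YFP+ replicate 3 (0.313). Testing against a log2 difference of 0.5 (treat) left 42 genes, a stricter hypothesis by construction. Camera with an estimated correlation left 1 list. The estimate was 0.60 for the pan-leukocyte list, far above the preset 0.01, but -0.027 for the glycolysis list, which lost its call too. A high estimate alone therefore does not account for the losses, and their cause was not tested further. Without both YFP+ replicates the p53, TGF-beta, scavenger receptor and coagulation calls ended (adjusted p = 0.336, 0.364, 0.326 and 0.0707), and the stellate and oxidative phosphorylation lists passed (0.0213 and 0.0238). Fry also called the angiocrine list (0.0236). With the replicate number as a block, 241 genes (204 higher and 37 lower), 180 at 2-fold or more and 22 lists were called. Of the 340 genes of the main fit, 202 kept their call with the block, and 12 named genes lost theirs. Same-numbered arrays had residual correlations of 0.159, 0.019, 0.0999 and 0.078, and 7 of 8 arrays correlated best with their own number, as a hint from the data, not the design. Other settings kept these totals within 1.5 times: quantile normalization 285, 180 and 22, cyclic loess 306 (267 higher and 39 lower), 192 and 21, dim genes left out 343, 210 and 18, mean of probe sets 341, 204 and 22, trended and robust eBayes 394, 238 and 23, all probe sets apart 354 and 211, and fry 21 lists. Of 64 named genes with a call, 28 kept it under every setting that tested them, among them Ccl3, Ppbp, Pf4, Laptm5, Cd53, Krt7, Cdh1 and Egfem1, and Tek, Alb and Mcpt8 did not. The other deposited table gave no further value, being identical, and normexp was not run because the values were normalized already. Signal over background limits dim genes, whose folds are probably compressed.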

Other observations

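The families and genes named in this part, and the test on the reporter features, were chosen after their values were seen.

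Some gene families had several members with a call; having been picked for it, they were not tested for enrichment. Of 28 semaphorin and plexin genes, which encode guidance cues and their receptors, 5 were called lower: Sema3d fell by 0.66, Sema3f by 0.51, Sema6a by 0.60, Sema6d by 0.66 and Plxna1 by 0.83 on the log2 scale. Of 33 chemokine genes whose symbols start with Ccl or Cxcl and a number, 4 were called higher, with Ccl4, Ccl6 and Ccl9 at 8.06, 6.77 and 5.15 fold beside Ccl3. The chemokine genes Ppbp and Pf4 were called higher too, but have other symbols and are not in this count. Of 47 keratin genes 4 were called higher, Krt8 at 3.29-fold beside Krt7, Krt18 and Krt19. All 13 called genes in these family counts kept their direction after quantile normalization and after cyclic loess, while Plxna1 and Sema3f lost their calls under both (limma adjusted p = 0.0517 and 0.0513, then 0.0672 and 0.0779).

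Single genes that were called higher in YFP+ cells included the following, picked by eye and, except for Tspan8, outside the fixed lists. Muc1 was 4.37-fold, Tff2 4.86-fold, Dmbt1 4.59-fold and Prom1 3.25-fold higher. Tspan8, at 4.19-fold, is on the bile duct list and already counted among its 6 called genes. Cyp11a1, the enzyme that starts steroid hormone synthesis, was 9.81-fold higher, and Alox15, Cd200r3 and Padi2 were 5.93, 7.43 and 8.45 fold higher. Of the 269 genes higher in YFP+ cells, 151 (56.1%) had their highest value on replicate 2, and 45, 36 and 37 on replicates 1, 3 and 4.

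As a hypothesis, the 3 reporter sets that were higher in YFP+ samples may come with the blood-cell genes. Their mean ranged over 1.57 log2 across the 4 YFP+ samples, close to the range of the pan-leukocyte list (1.66) and 3.79 times that of the pan-endothelial list (0.415), and all 4 samples had the same order for this mean and pan-leukocyte genes (chance 0.0417). The set with the 3.09-fold difference did not have this order by itself (312.8 units on replicate 1, 321.2 on replicate 3). Hepatocyte genes did have it (8.07, 8.65, 7.75 and 8.33 log2 on replicates 1 to 4), so it is not particular to blood-cell genes. The ratio of 3.79 stayed below the 4 set for the test, which also asked for 1 order in all 3 sets, so the source of the reporter transcript cannot be told apart.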
